A study of Mus musculus with 3 samples.

How the data were processed

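RNA from naive CD4+ T cells of C57BL/6 mice was measured on 3 arrays: 1 of cells cultured with medium and vehicle, 1 with IL-21, and 1 with IL-6 and TGFb1. Per the labels' protocols, the RNA was fragmented and biotin-labelled with an Affymetrix whole-transcript terminal labelling kit and hybridized by a service company. The deposited values are intensities, 1 for each of 28815 probe sets on each array. The unit was read from the values, which were all above 0, ran from 25.5 to 20652 and had medians of 191, 182 and 188. Per the submitters' processing notes the genome build was mm8, and no coordinates were used here. The method by which the authors summarized and normalized the intensities is not given in the sources used here. The sorted values of the 3 arrays were close to each other, but 2908 probe sets had exactly equal values on all 3. Between IL-21 and medium 19.1% of probe sets were exactly equal, between IL-6 with TGFb1 and medium 16.4%, and between the treated arrays 21.6%. Such ties put many small differences at 0. The arrays' number limits the precision, since with 1 array per group neither the spread between cultures nor that between arrays can be estimated.

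Probe sets were named from the platform annotation: 21780 had 1 gene symbol, 1605 had several and 5430 had none listed. Only those with 1 symbol were used for genes. Of these, 21689 matched a gene by Entrez identifier in a RefSeq gene table (assembly GRCm38.p6, used for names alone), and 0 symbols changed. They covered 19935 genes, of which 998 had several probe sets, and the probe set with the highest mean over the 3 arrays stood for the gene. Genes with no probe set of exactly 1 symbol were not analysed here. The plan had allowed for a table of log2 values, or for log2(value + 1) if the table was linear. It was linear, so log2(intensity + 1) was used, which slightly understates differences of dim genes. A gene was compared if its highest value over the 3 arrays was at or above the median of all values, an intensity of 187, which kept 11003 genes. No further normalization was applied.

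The groups were taken from the labels, and 3 comparisons were made: IL-21 minus medium, IL-6 with TGFb1 minus medium, and IL-21 minus IL-6 with TGFb1. As there was 1 array per group, no test was possible, and genes with a log2 difference of at least 1 or at most -1 were counted as at least 2-fold higher or lower. For scale, the 474 genes with 2 bright probe sets showed a median gap between them of 0.07 in IL-21 minus medium, with a 95th percentile of 0.41, which covers probe set error within the same arrays and not the spread between cultures. The named genes followed a rule. In each comparison they were the 12 highest and 12 lowest differences past 2-fold (8 and 8 between the treated cultures), without provisional symbols, small RNAs and olfactory or vomeronasal receptors. Up to 4 members of each described list with the largest differences were added, with a fixed set of cytokine, receptor and lineage genes. With IL-21 only 11 genes on the lower side met the rule. The 29 gene lists covered helper T cell lineages, cytokine signalling, metabolism, stress, proliferation and markers of other cell types. The median of each list over its compared genes was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 20 bins. A list with under 3 compared genes got no percentile. Percentiles were rounded, so that 100 can stand for a median above all but a few random lists. With 26 lists in each comparison, a few would lie outside the central 95% by chance. There were 10 with IL-21, 10 with IL-6 and TGFb1, and 12 between the treated cultures. Many lists share genes, such as Il21 and Maf, so they are not independent. Genes of a list can also move together, which the random lists leave out.

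For genes past 2-fold in both treatments, 100 simulated pairs of unchanged arrays against the same medium array gave the overlap expected from the shared control. The noise was set from the differences of all compared genes, with a robust estimate and with their standard deviation. The calculations were tested on 3 simulated arrays with 11075 genes, built from the mean of the 3 real arrays and the spread between them. That spread includes any real treatment differences, and changes were put into the simulated IL-21 array. Of the genes given a true 2-fold change, 57.5% came out past 2-fold, and of those given 3-fold or more, 100%. Of 10876 unchanged genes, 2 passed. A list of 20 genes whose computed differences were shifted by 0.3 log2 units reached percentile 100, and 3% of 200 unshifted lists fell outside the central 95%. The unshifted lists were random draws of independently simulated genes, so these results check the calculation alone. They do not show how often lists of genes that move together would fall outside.

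The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring each array on its median, and loess centring of the differences with a span of 0.3. Others were no brightness filter, a filter on the mean, a filter at the 75th percentile, the mean of all probe sets of a gene, and values below the 20th percentile raised to it. The last were log2(value + 16), thresholds of 1.5-fold and 3-fold, and random lists not matched on brightness. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.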

Results

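Gene expression was measured in naive CD4+ T cells, the helper lineage of T lymphocytes before they meet antigen, from wild-type C57BL/6 mice 8 weeks old. The cells were cultured with medium and vehicle, with the cytokine IL-21, or with IL-6 together with TGFb1, the cytokine pair commonly used to obtain Th17 cells in culture. The labels do not give the time in culture, the cytokine doses or whether the T cell receptor was stimulated. Each culture condition was measured on 1 array, so there were 3 arrays and no replicates. No difference below has a replicate error or a p-value, and each one compares 2 arrays. The values were probe set intensities on a linear scale. Their median was 191 on the medium array, 182 on the IL-21 array and 188 on the IL-6 and TGFb1 array. On the medium array the cytokine genes Il2 (2445) and Ifng (1153) were above that array's 75th percentile of 750. The cells of the medium culture should therefore not be assumed to be resting. Differences are given as log2(intensity + 1) of one array minus the other, and 11003 genes bright enough on at least 1 array were compared. The arrays were very alike: across all probe sets Pearson's r of the log2 values was 0.996 between IL-21 and medium, 0.995 between IL-6 with TGFb1 and medium, and 0.997 between the treated cultures. These correlations are across probe sets, which are not independent replicates. Of the compared genes, 96.2% lay within 0.5 log2 units of medium with IL-21 and 95.1% with IL-6 and TGFb1.

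The comparison of IL-21 with medium asks which transcripts differ when naive CD4+ T cells are cultured with this cytokine. The highest difference of all compared genes was that of Il21 itself, which encodes the cytokine: its intensity was 43.0 with medium and 1780 with IL-21, a log2 difference of 5.34. The medium value was dim, below that array's 25th percentile of 83.8, and the difference was 4.67 when low values were raised to the 20th percentile of all values. Il23r, a subunit of the IL-23 receptor, had a difference of 2.41 from a medium intensity of 77.9 that was dim as well, and Ahr, a ligand-activated transcription factor used by Th17 cells, was 3.59-fold higher (1.84). Socs3, a feedback inhibitor of STAT3-activating cytokine receptors, was 2.86-fold higher (1.52). Among the genes lower with IL-21 were Eomes, a T-box transcription factor of cytotoxic and memory T cells (-1.83), and Ifng, which encodes interferon gamma (-1.16).

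With IL-21, 53 genes were at least 2-fold higher and 12 at least 2-fold lower than with medium. Beside Il21, Il23r and Ahr, the genes with the highest differences were Plac8 (2.21), the cysteinyl leukotriene receptor gene Cysltr2 (2.16, from a dim medium intensity of 59.8, and 1.96 when low values were raised), Gatm, an enzyme of creatine synthesis (2.14), and the immunoglobulin-like receptor gene Lilr4b (2.14). They were followed by the transglutaminase gene Tgm2 (2.08), the insulin-like growth factor binding protein gene Igfbp4 (1.98), Cysltr1, the other leukotriene receptor gene (1.81), Lilrb4a (1.71) and Gzma, which encodes granzyme A (1.68). On the lower side, Ccdc141 had a difference of -1.79, and its 5 probe sets lay between -2.20 and -1.42. The urokinase receptor gene Plaur (-1.62), Ifi203 of the interferon-inducible p200 family (-1.42), Cd83 (-1.27), Prp2 (-1.19) and Pld4 (-1.19) were also lower. The remaining named genes were the costimulatory ligand gene Cd80 (-1.16), Igfbp7 (-1.13) and Lad1 (-1.11). The dimmer probe set of Cd80 gave -0.45, and that of Socs3 gave 0.86.

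Gene lists fixed in advance were described by their median difference and by its percentile among random lists of equal size and brightness. Counts of genes above or below 0 are not to be read against an even split. Over all compared genes the median difference was 0.04 with IL-21, 0.02 with IL-6 and TGFb1 and 0.00 between the treated cultures. Exactly 0 were 11.6%, 7.1% and 13.0% of these differences. Of the 21 compared genes in the list of STAT3 targets and cytokine feedback genes, 17 were above 0 with IL-21, with a median of 0.28 above all 10000 random lists. Socs3, Bcl3 (1.12) and Fosl2 (1.08), the latter transcription regulators of the NF-kB and AP-1 families, were at least 2-fold higher and no member was 2-fold lower. Bcl6, the repressor that marks follicular helper T cells, had a difference of 0.77. In the Th17 list 4 of 16 genes were at least 2-fold higher, namely Il21, Il23r, Ahr and Il24 (1.06), and the list median was 0.22 (percentile 99.9). Il24 was dim with medium, at 116, and fell just short of 2-fold with log2(value + 16). The cytokine genes Il17a (-0.48) and Il17f (0.21) were within 2-fold of medium, and both were below the brightness filter of 187 on these 2 arrays, so their differences are poorly measured.

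The glycolysis and hypoxia list had 22 of 25 genes above 0 with IL-21 and a median of 0.19, above all random lists, although no member reached 2-fold. Its highest members were the mitophagy receptor gene Bnip3 (0.96), the aldolase gene Aldoc (0.85) and the lactate transporter gene Slc16a3 (0.83). The Th2 list had 11 of 12 genes above 0 and a median of 0.28 (percentile 100), with the transcription factor Nfil3 at 0.94, the cytokine Il4 at 0.79 and Gata3, the main Th2 transcription factor, at 0.70. The naive and quiescence list had a median of 0.18 (percentile 100), with Igfbp4 as its only gene past 2-fold. Its members went both ways, with 13 of 20 genes above 0 and 6 below, among the latter Klf3 (-0.72) and Dapl1 (-0.70). In the Th1 and cytotoxic list the members went both ways. Gzma and the IL-18 receptor gene Il18r1 (1.18) were at least 2-fold higher, Eomes and Ifng were at least 2-fold lower, and the median was 0.14 (percentile 99.7). That percentile was 65.5 at its lowest among the other settings. The interferon response list lay below all random lists, with a median of -0.06 and 17 of 26 genes below 0. Its median was 0.01 when each array was centred on its median, and none of its members reached 2-fold. The members with the largest differences went both ways, with Ddx58 (0.66) and Ifit2 (0.37) above medium and Irf8 (-0.51) and Iigp1 (-0.43) below. The receptor genes of the added cytokines were within 2-fold of medium: 0.46 for Il21r, 0.38 for Il6ra, 0.05 for Il6st, -0.01 for Tgfbr1 and 0.11 for Tgfbr2.

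The comparison of IL-6 and TGFb1 with medium describes the Th17-inducing culture on the same footing. Il21 was again the gene with the highest difference, 6.13 on the log2 scale, with an intensity of 3073, and 5.46 when low values were raised. Il23r had a difference of 4.34, with an intensity of 1596 against the dim medium value of 77.9. Il17f, which encodes the Th17 cytokine IL-17F, was 11.8-fold higher (3.56, from an intensity of 160 to 1896), and Ahr was 7.43-fold higher (2.89). The transcription factor gene Maf was 6.81-fold higher (2.77). Eomes was 8.98-fold lower (-3.17) and Ifng 3.97-fold lower (-1.99).

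With IL-6 and TGFb1, 74 genes were at least 2-fold higher and 40 at least 2-fold lower than with medium. Named genes on the higher side also included Cysltr1 (4.22), Timp1, an inhibitor of matrix metalloproteinases (2.99), the membrane protein gene Emp1 (2.87), Gatm (5.67-fold), the kinase gene Alpk2 (2.41), Igfbp4 (2.31) and the serpin gene Serpinb5 (2.26, from a dim medium intensity of 52.4, and 1.87 when low values were raised). On the lower side were Nrn1, which encodes neuritin (-2.69), Ifi203 (-2.68), Lad1 (-2.45), Ccdc141 (-2.29), Dapl1 (-2.24) and the T cell receptor adaptor gene Trat1 (-2.07). They were followed by the chemokine gene Ccl3 (-1.94), Ms4a4c (-1.90), Cd83 (-1.90) and Ms4a4b (-1.84).

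All 16 compared genes of the Th17 list were above 0 with IL-6 and TGFb1, 7 of them at least 2-fold, and the median of 0.71 was above all random lists. Besides Il21, Il23r, Il17f, Ahr and Maf, these were Rora, a nuclear receptor of the Th17 program (1.79), and the cytokine gene Il9 (1.24). Rora was outside the naming rule and was named after its values were seen. Il17a was within 2-fold of medium, with intensities of 175 and 193 and a difference of 0.15. The STAT3 and feedback list had a median of 0.20 (percentile 100), with Maf, Socs3 (1.52), Fosl2 (1.15) and Bcl3 (1.11) at least 2-fold higher. Bcl6 had a difference of 0.64. The list of TGF-beta targets and regulators had a median of 0.15 (percentile 99.3). Its highest members were the TGF-beta target gene Pmepa1 (0.98) and the helix-loop-helix inhibitor gene Id2 (0.98), while the semaphorin co-receptor gene Nrp1 (-1.76) and Lrrc32 (-1.34), which encodes the latent TGF-beta anchor GARP, were at least 2-fold lower.

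The interferon response list lay below all random lists with IL-6 and TGFb1, with a median of -0.18, 19 of 26 genes below 0 and Isg20, an exonuclease, at least 2-fold lower (-1.05). Ifih1 (-0.67) and Iigp1 (-0.65) were lower as well, while Ddx58 was above medium (0.55). The T cell activation list had a median of -0.04 (percentile 0.19), with Cd83, Tnfsf11, which encodes RANK ligand (-1.13), and Il3 (-1.04) at least 2-fold lower. Il3 was dim with medium (129) and with IL-6 and TGFb1 (62.2), and it was within 2-fold when low values were raised. In the Th1 and cytotoxic list 4 genes were at least 2-fold lower, namely Eomes, Ifng, Ccl3 and Nkg7, the latter being a cytotoxic granule protein gene (2.01-fold), and 1 was higher, Il18r1 (1.97). Nkg7 fell just short of 2-fold with log2(value + 16) and when each array was centred on its median. The median of that list, 0.12 (percentile 98.8), had the opposite sign to its mean of -0.22 and was -0.09 with the stricter brightness filter. It stayed above the central 95% of random lists in only 6 of the 10 other settings, with a percentile as low as 0.32. The Th2 list had Gata3 at -1.74 and the enkephalin precursor gene Penk at -1.54, with Il9 on the higher side. Its median was -0.06 (percentile 1.96), and its percentile reached 15.8 among the other settings. In the regulatory T cell list Foxp3, the lineage factor, had a difference of -0.84, after -0.66 with IL-21. The list median was -0.02 (percentile 3.09), and 0.01 (percentile 21.7) with IL-21. The naive and quiescence list had a median of 0.15 (percentile 99.8), but its members went both ways, with Igfbp4 (2.31) and the sphingosine phosphate receptor gene S1pr1 (1.12) higher and Dapl1 and Klf3 (-1.15) lower. The list of common gamma chain and other cytokine receptors had a median of 0.17 (percentile 99.9, and 70.4 with no brightness filter), with Il23r and Il18r1 past 2-fold. The receptors of the added cytokines were within 2-fold of medium, at 0.34 for Il6ra, 0.00 for Il6st, -0.01 for Tgfbr1, 0.18 for Tgfbr2 and 0.26 for Il21r.

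Many of the genes far from medium were the same in both treated cultures. Of the compared genes, 32 were at least 2-fold higher in both, among them Il21, Il23r, Ahr, Cysltr1, Cysltr2, Gatm, Igfbp4, Socs3 and Il18r1. A further 10 were at least 2-fold lower in both, among them Eomes, Ifng, Ccdc141, Ifi203, Lad1, Plaur, Cd80 and Cd83. The difference was larger with IL-6 and TGFb1 in 22 of the 32 genes higher in both and in 9 of the 10 lower in both. Socs3 had a difference of 1.52 in each treated culture, where its dimmer probe set gave 0.86 with IL-21 and 0.56 with IL-6 and TGFb1. Of the 21 genes at least 2-fold higher with IL-21 but not with IL-6 and TGFb1, 19 were still above 0 with the latter. Both differences subtract the same medium array, which by itself favours the same sign. Only Ajuba, a LIM domain scaffold protein gene, was past 2-fold in opposite directions, at 1.58 with IL-21 and -1.38 with IL-6 and TGFb1.

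Independent lists of these sizes would share 0.356 higher and 0.0436 lower genes. Both comparisons use the same medium array. Simulated arrays with no effect, compared with a simulated medium array, shared at most 1 gene in each direction in 100 draws. They had almost no genes past 2-fold to share, however, with a mean of 0 under the robust noise estimate and 2.16 under the standard deviation. The simulated counts leave out real effects and any trait of the real medium array, and the independent counts leave out the shared array. Part of the excess may therefore come from the medium array, which could not be split. Across genes, the correlation of the differences was 0.75 and their covariance was 0.0480. The simulated arrays all had equal noise, which by itself fixes their correlation near 0.50, the value they gave. Their covariance was 0.00799 with the robust noise estimate and 0.0256 with the standard deviation. A medium array noisier than the treated arrays would give higher values than these, so the simulation cannot separate a shared response from that array.

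**Figure D1:**
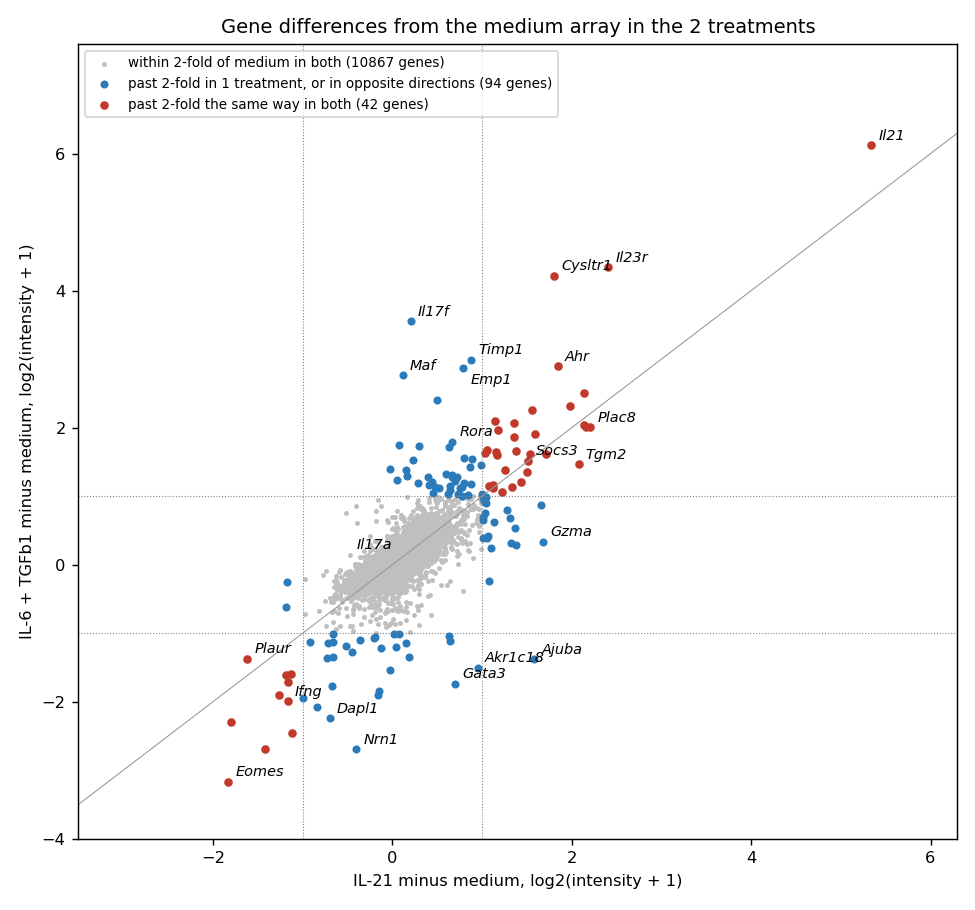
Each point is 1 of the 11003 compared genes, placed by its difference from the medium array in log2(intensity + 1) with IL-21 on the horizontal axis and with IL-6 and TGFb1 on the vertical axis. Dotted lines mark 2-fold and the diagonal marks equal differences. The 42 genes past 2-fold the same way in both treatments are red, and Il17f, Maf, Timp1 and Emp1 stand above the diagonal, within 2-fold of medium with IL-21.

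The direct comparison of the treated cultures asks where IL-21 differs from IL-6 with TGFb1, and it does not use the medium array. These cultures differ both in IL-21 against IL-6 and in the addition of TGFb1. No array had IL-6 alone, TGFb1 alone or IL-21 with TGFb1, so these differences cannot be told apart. With IL-21, the Th17 genes Il17f (-3.35), Maf (-2.65), Il23r (-1.93), Rora (-1.12) and Ahr (-1.05) were lower, as were Cysltr1 (-2.41), Timp1 (-2.11), Emp1 (-2.08), Alpk2 (-1.90) and the transporter gene Slc4a11 (-1.68). Ajuba (2.96), the steroid-metabolizing enzyme gene Akr1c18 (2.46), Gata3 (2.43) and Nrn1 (2.29) were higher. The anticoagulant protein S gene Pros1 (1.76), Ms4a4c (1.74), Ms4a4b (1.69) and Il3 (1.67, and 1.52 when low values were raised) were also higher with IL-21. In all, 29 genes were at least 2-fold higher and 21 at least 2-fold lower with IL-21 than with IL-6 and TGFb1.

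In the Th17 list 13 of 16 genes were lower with IL-21, 7 of them at least 2-fold, and the median of -0.75 lay below all random lists. The list of TGF-beta targets and regulators had 17 of 24 genes lower with IL-21 and a median of -0.11 (percentile 0.0100). The STAT3 and feedback list did not stand apart between the treated cultures, with a median of 0.02 (percentile 81.9). The Th2 list was higher with IL-21, with a median of 0.34, and Gata3, Penk (1.51) and Il4 (1.17) past 2-fold against Il9 on the lower side (-1.19). The T cell activation list had 21 of 28 genes higher with IL-21 and a median of 0.18, and the Th1 and cytotoxic list had 14 of 21 and a median of 0.20. The glycolysis and hypoxia list had 20 of 25 genes higher with IL-21 and a median of 0.14. Each of these medians lay above all random lists. The cholesterol synthesis list had 17 of 19 genes higher and a median of 0.14 (percentile 100), with no gene past 2-fold. The interferon response list had 19 of 26 genes higher with IL-21 and a median of 0.08 (percentile 100), and its percentile was 95.2 with the stricter brightness filter. The naive and quiescence list was lower, with a median of -0.07 (percentile 0.0400), although its mean was 0.02.

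**Figure D2:**
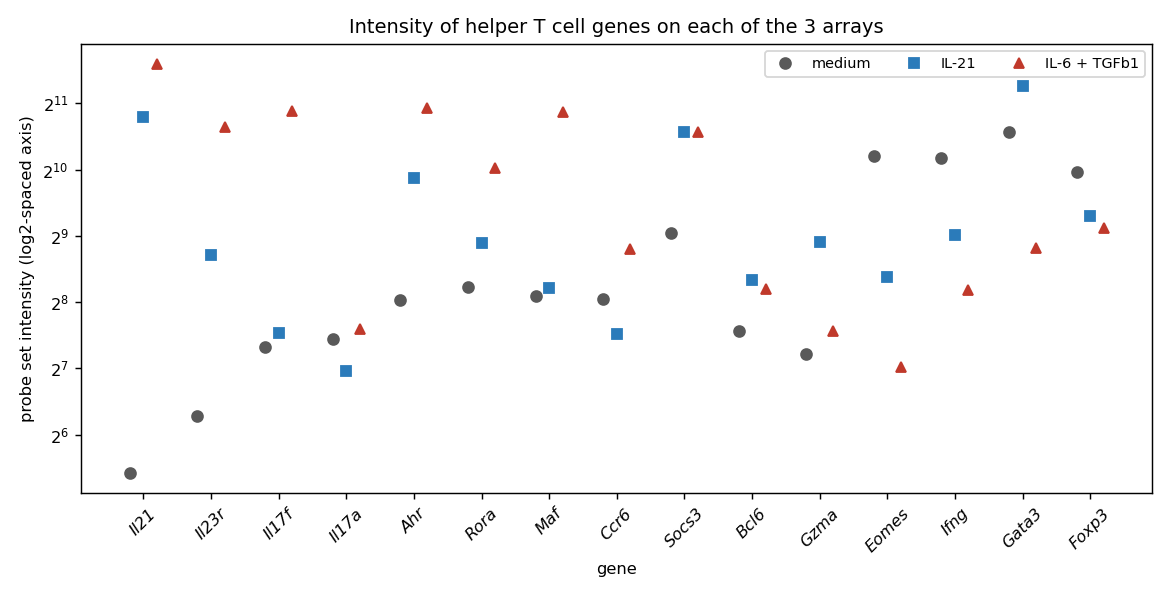
Probe set intensity (log2-spaced axis) of 15 helper T cell genes on the medium, IL-21 and IL-6 with TGFb1 arrays, 1 point per array. Il21 and Il23r were above medium on both treated arrays, Il17f and Maf on the IL-6 and TGFb1 array, and the 3 points of Il17a lie within 2-fold of each other.

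The remaining lists and comparisons were as follows. The cell cycle list had a median of 0.06 in each treated culture (percentiles 99.8 and 99.6, but 79.7 and 84.6 among random lists not matched on brightness) and 0.00 between them, with no gene past 2-fold. The follicular helper list had medians of 0.09 with IL-21 (percentile 91.9) and -0.03 with IL-6 and TGFb1 (percentile 3.06), and 0.05 between them. Its mean of 0.47 with IL-6 and TGFb1, set by Il21 and Maf, had the opposite sign to its median. Glycolysis and hypoxia genes had a median of 0.01 with IL-6 and TGFb1 (percentile 58.7). Cholesterol synthesis genes had medians of 0.10 with IL-21 and -0.02 with IL-6 and TGFb1, inside the central 95% of random lists. The TGF-beta list with IL-21 (0.07), the T cell activation list with IL-21 (0.03) and the cytokine receptor list with IL-21 (0.06) were inside it as well. So were the lists of apoptosis and survival genes (0.03 and 0.00), chemokine receptors (0.03 and -0.03), unfolded protein response genes (0.00 and 0.00) and heat shock and immediate early genes (0.02 and -0.01), with IL-21 and with IL-6 and TGFb1 respectively. The unfolded protein response list with IL-21 left that range in 5 of the 10 other settings, with a percentile as low as 0.0400. The follicular helper list left it in 2 settings with IL-21 and 1 with IL-6 and TGFb1, and the chemokine receptor and heat shock lists in 1 each with IL-6 and TGFb1. Between the treated cultures the follicular helper list (percentile 97.28) left it in 2 settings, with a percentile up to 97.92. The regulatory T cell list between them (percentile 86.16) left it in 1 setting, with percentiles from 7.05 to 99.965 over the settings. Ribosomal protein genes had medians of 0.00 and 0.02, and of -0.02 (percentile 0.78) between the treated cultures, where the sign turned to 0.02 when each array was centred on its median and 3 of the 10 other settings put it inside the central 95% (percentile up to 14.7). Other lists whose mean and median differed in sign were the chemokine receptor and heat shock lists with IL-6 and TGFb1, the regulatory T cell list with IL-21, and the STAT3, follicular helper, cytokine receptor, chemokine receptor, cell cycle and apoptosis lists between the treated cultures. The replication-dependent histone list had 0 compared genes.

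**Figure D3:**
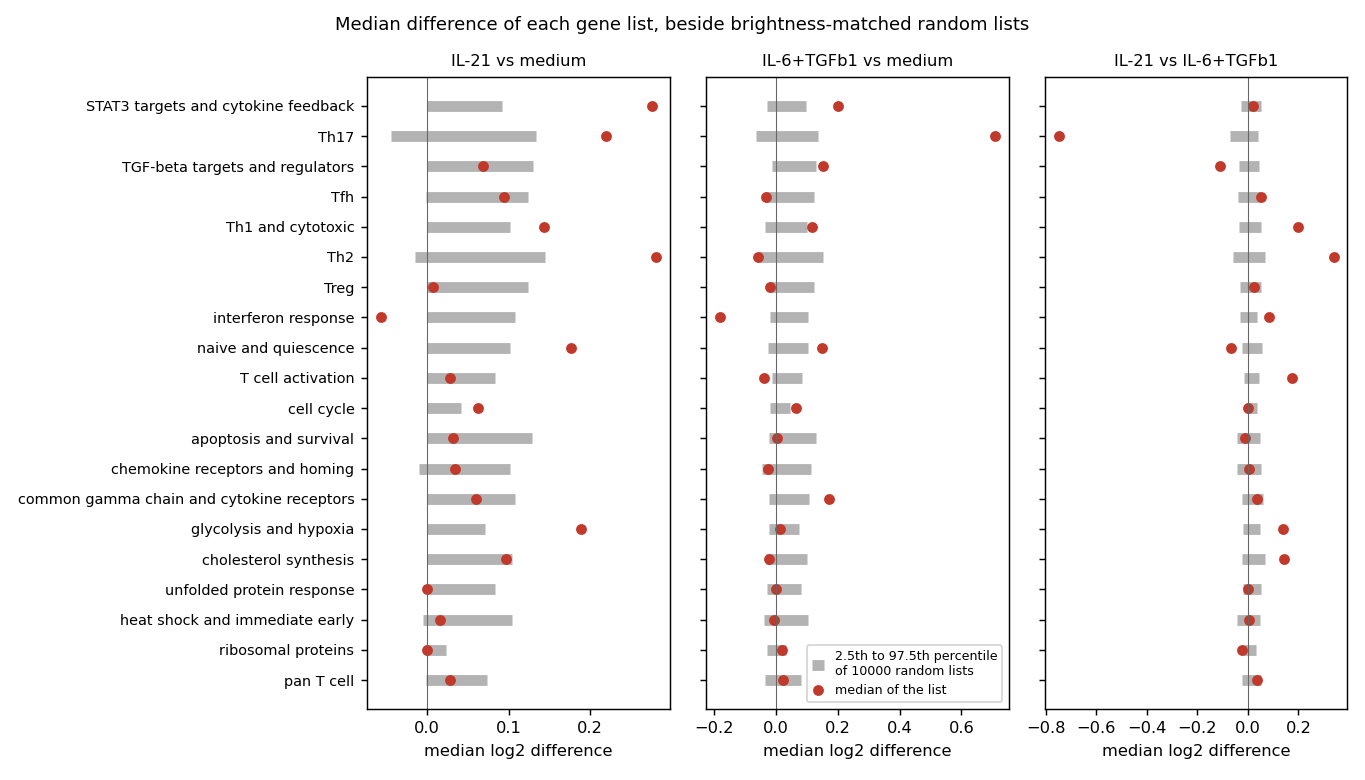
Median log2 difference of each gene list (red points) in the 3 comparisons, over grey bars that span the central 95% of 10000 brightness-matched random lists. The Th17 list stands farthest from its bar with IL-6 and TGFb1 (0.71) and between the treated cultures (-0.75), and the panels have different horizontal scales.

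Genes that mark T cells and other cell types were read in the same way. The pan T cell list of 18 genes had medians of 0.03 with IL-21 and 0.02 with IL-6 and TGFb1, and Trat1 was its only gene past 2-fold. Cd8b1, the compared gene of the CD8 T cell list, had an intensity of 810 with medium and differences of -0.15 and -0.39, beside the lower Eomes, Ifng and Ccl3 values. Cd8a, the other gene of that list, was below the brightness filter on every array, with differences of -0.16 and -0.07. The natural killer and innate-like list had 2 compared genes, with medians of -0.03 and 0.02. The dendritic cell list had a median of -0.21 with IL-21 (percentile 0.31) and -0.10 with IL-6 and TGFb1 (percentile 4.01, and outside the central 95% in 2 other settings, down to 0.59), and its gene past 2-fold in each was Cd83, which activated T cells also express. The stromal and endothelial list of 6 dim genes had a median of -0.22 with IL-21 (percentile 1.43) and -0.09 with IL-6 and TGFb1. B cell genes (medians 0.02 and 0.06), plasma cell genes (0.09 and -0.02), monocyte, macrophage and neutrophil genes (-0.05 and -0.06) and erythroid and platelet genes (-0.20 and -0.03) were inside the central 95% in both. The B cell, monocyte and erythroid lists with IL-21 left it in 1 other setting each. The mean had the opposite sign to the median in the pan T cell list in both treatments and in the B cell and plasma cell lists with IL-6 and TGFb1. Between the treated cultures the B cell and plasma cell lists had medians of 0.16 (percentile 98.9) and 0.12 (percentile 99.6, and 62.3 at its lowest among the other settings). Of genes with a probe set, 5 of 18 were compared in the B cell list and 7 of 9 in the plasma cell list. In the monocyte list 3 of 24 were compared and in the erythroid list 3 of 10. The B cell genes compared were Cd79b, Cd74, H2-Ab1, H2-Aa and H2-Eb1, while Cd79a, Ms4a1, Pax5, Cd22 and Blk were too dim.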

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

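No test was chosen for these values after they were seen: the brightness filter and the 2-fold threshold were those used for genes. Probe sets with no gene symbol or with several symbols took no part in the comparisons. Of them, 1980 without a symbol and 845 with several passed the brightness filter, and 8 were at least 2-fold above the medium array in a treated culture. Of the 7 without a symbol, the highest difference was 3.29 with IL-6 and TGFb1, from an intensity of 140 to 1376, and 1.75 with IL-21. Another had 2.68 with IL-6 and TGFb1 and 1.75 with IL-21. A group of 3 had nearly the same difference in both treatments: 1.91 with IL-6 and TGFb1 against 1.87 with IL-21, 1.40 against 1.37, and 1.40 against 1.38. The other 2 differed from medium mainly with IL-6 and TGFb1, at 1.47 against 0.07 with IL-21 and at 1.32 against 0.26. The probe set of several genes had its larger difference with IL-21, at 1.33, against 1.05 with IL-6 and TGFb1. The genes behind these signals were not identified here, and no explanation was tested.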

How the results depend on the processing

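All alternatives reported here were chosen beforehand. No paired analysis was possible because each group had 1 array, and none could be left out. Normalization, pseudocount, floor and probe set choices, no filter and the filter on the mean left every count of genes within 1.5 times its value. Fewer genes were compared with the filter at the 75th percentile (5616). It gave 27 higher and 7 lower with IL-21, 42 and 26 with IL-6 and TGFb1, 19 and 11 between the treated cultures, and 6 lower in both treatments. A 1.5-fold threshold gave 224 and 55, 287 and 110, and 101 and 58, with 139 higher and 30 lower in both. A 3-fold threshold gave 14 and 3, 31 and 17, and 8 and 8, with 11 higher and 2 lower in both. The share of higher genes with IL-21 lay between 75.4% and 85.0% over all settings, against 81.5% as reported. Of 2934 recomputed differences of named genes, 2910 moved by less than the robust spread of all genes, 24 moved by more and 0 past 2-fold turned sign. Il21 with IL-21 was 4.67 with low values raised and 4.93 with log2(value + 16). Averaging probe sets put Cd80 with IL-21 at -0.81. Of 696 recomputed list medians, 142 moved by more than the spread of random lists and 33 turned sign, 30 of them of lists inside the central 95% of random lists and 3 of lists outside it. Centring on the median gave the interferon response list 0.00931 with IL-21 and the ribosomal list 0.0194 between the treated cultures; the 75th percentile filter gave the Th1 and cytotoxic list -0.0912 with IL-6 and TGFb1. The cause was not tested. Of 32 list medians outside the central 95% of random lists, 23 stayed on their side in every setting that gave a value, which was 9 of 10 for the stromal list: with the 75th percentile filter the stromal and erythroid lists had no genes left. Low signal limits the differences of dim genes: Il21 with medium, at 43.0, lay below the brightness filter of 187, so its difference is imprecise.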

Other observations

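The tests of explanations in this part were all chosen after the results were seen, and the genes named in the opening paragraph were chosen after their values were seen.

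Most genes past 2-fold were in none of the fixed lists: 52 of 65 with IL-21 and 85 of 114 with IL-6 and TGFb1. Some of these genes are given here as values, not as a theme that was tested. Ctla2a, a cathepsin inhibitor gene, had differences of 1.36 with IL-21 and 2.07 with IL-6 and TGFb1, its relative Ctla2b -0.03 and 1.40, and Cst7, which encodes cystatin F, 1.33 and 1.13. The serpin genes Serpinb5 (1.55 and 2.26) and Serpinb1a (0.64 and 1.72) were above medium. Ctla2a, Serpinb5 and Serpinb1a were dim with medium, at 75.9, 52.4 and 95.3. Serpinb9, the granzyme B inhibitor, and Serpinb6b had -0.12 and 0.04 with IL-21 and -1.22 and -1.21 with IL-6 and TGFb1. Tnfrsf8, which encodes CD30, was higher in both (1.43 and 1.21), and its ligand gene Tnfsf8 was near medium with IL-21 (0.15) and lower with IL-6 and TGFb1 (-1.14). The metallothionein gene Mt2 was higher in both (1.14 and 2.10), and so was Gadd45g, a stress-induced growth regulator (2.83-fold and 2.56-fold). Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha, had 1.08 with IL-21 and -0.24 with IL-6 and TGFb1.

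A few genes lay on opposite sides of medium. With at least 0.5 log2 units on each side, there were 6. Ajuba, Akr1c18 (0.95 and -1.50), Gata3 (0.70 and -1.74), Il3 (0.63 and -1.04) and Pros1 (0.64 and -1.12) were higher with IL-21 and lower with IL-6 and TGFb1, and the chemokine receptor gene Ccr6 had the reverse order (-0.52 and 0.76). Of these, Ajuba alone passed 2-fold on both sides.

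The 42 genes past 2-fold in both treatments could have come from the medium array alone if that array stood apart for a technical reason. The test took it that the treated arrays would then differ over these genes no more than over random genes of the same brightness. Their median size of difference between the treated arrays was 0.45, where matched random lists had 0.07 and at most 0.15. However, the 42 genes were picked as extreme on these same arrays, and the random lists were matched on brightness and not on variability. Genes that vary more between any arrays would give such a gap too. The test therefore cannot decide whether the medium array was the only cause. For 17 of the 42 genes, among them Socs3, Bcl3 and Fosl2, the treated arrays differed by no more than 0.32, the 95th percentile of all compared genes. It also stays open that the medium array adds to each difference, and a response of the cells to both treatments remains a hypothesis that replicate cultures would test.

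More genes were past 2-fold on the higher than on the lower side, which a brightness-dependent shift between arrays could produce. After loess centring removed such a trend, 76.2% of 63 genes were higher with IL-21 (exact 95% binomial interval 63.8% to 86.0%) and 63.2% of 114 with IL-6 and TGFb1 (53.6% to 72.0%). The intervals treat genes as independent, which they are not. They therefore cannot decide whether the excess goes beyond variation between arrays. On these arrays an excess remained after a smooth trend was removed, with 48 genes higher and 15 lower with IL-21, and 72 and 42 with IL-6 and TGFb1. Other differences between single arrays stay open.

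Il17a was within 2-fold of medium with IL-6 and TGFb1 (0.15) although Il17f, Il23r, Rora and Maf were not. A probe set that responds poorly to its transcript is a candidate explanation, and so is a culture that had little Il17a transcript when it was harvested. Il17a had 1 probe set, and no array here is known to hold much of its transcript, so these cannot be told apart.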
